A study of Rattus norvegicus with 12 samples.

How the data were processed

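RNA from hind leg muscle was hybridised to Affymetrix microarrays, 1 array per pool. Per the submitters' processing notes the arrays were processed with RMA in R 3.2.2; the RMA version and the genome build are not given in the sources used here. The deposited values are log2 expression values per probe set. The authors removed control probe sets and those without detection on enough arrays of each group, per the deposited descriptions, which left 18957 of 29214 probe sets. The deposited value table and the table of detected probe sets hold the same values. The authors also deposited a table of 895 probe sets with their p-values, linear group means (intensity scale, 2 to the power of the mean log2 value) and the ratio of these means, per the file headers. These were chosen by the authors with SAM and a p-value for low protein against control, and kept where the gene was known, per the deposited descriptions.

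Groups were taken from the sample labels, and all 12 arrays entered 1 fit per probe set in limma 3.58.1 (R 4.3.3), with 3 group means, eBayes without trend or robust options, and Benjamini-Hochberg adjustment over all 18957 probe sets. Tests are two-sided and the threshold was an adjusted p of 0.05. All values come from the deposited log2 values without a further transformation. As removal of control probe sets could not be checked against an annotation, the deposited selection was used as it stands. Replicate numbers stand for different dams. Their deviations from the group means were correlated above 0.1 in 3 of 12 same-number pairs, so they were not used to pair arrays.

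Gene symbols came from the platform annotation: 11721 probe sets had 1 symbol, 141 had several and 7095 were not listed. Among the latter, 328 were named through the authors' deposited table, among them Cidea, Lpcat2 and Zfp185. Identifiers matched the RefSeq gene table for 11702, and no coordinates are given because no genome build is named. A gene with several probe sets was represented by the one with the highest mean. Among probe sets identical on all arrays, 163 repeat another.

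Lists of genes and cell type markers and the alternatives named first below were fixed before the data were examined. The lists were tested with camera at a correlation of 0.01, with adjustment over 39 lists within a comparison. Camera compares the members of a list with all other genes, so a list can pass as lower while its members do not fall. Camera with an estimated correlation and fry, which tests the members against no change, were run beside the first. Lists of hepatocyte and pancreas markers were written after the values had been seen and were not part of the adjustment. A check of sex-specific genes was not run. Named genes were, per comparison, those with 1 symbol (not one of a predicted gene, an olfactory or vomeronasal receptor or a microRNA, by its prefix), adjusted p under 0.05 and no overlap between the arrays of the groups: the 12 largest rises and the 12 largest falls; where fewer than 6 passed in a direction, those with the smallest p filled up to 6 and are described as not passing. Up to 4 members with the smallest p of each list that passed and a fixed set of growth, taurine and muscle genes were added. Of that set, Myh8 has no probe set named here. Genes outside this rule, such as Alb, were chosen after their values were seen.

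The share of the low protein shift kept with taurine was measured on arrays not used to choose the probe sets. Unchanged groups were simulated 100 times from random normal combinations of each group's own deviations. This replaced, after its output had been seen, a simulation with random signs that gave group means of exactly 0 in some draws, and the observed covariance lay outside the range of that first simulation and lies within the range of the present one. For the adipocyte and early gene patterns the spread was taken over arrays, pooled within the 3 groups, in place of a spread over genes used at first and replaced after its result had been seen. The methods' t-test was run with equal variance and a t reference. Before use, the tests were checked on simulated data: with 18957 probe sets for low protein against control, 79% of changes of 0.5 and 97% of changes of 1 on the log2 scale were recovered, with 8 false calls among 184.

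The alternatives fixed at the start were the replicate block, only the groups compared, the trend and robust options, a level filter, only probe sets with 1 symbol, quantile normalization, median centring, array weights, the table of all probe sets, other thresholds and leaving out each array. Cyclic loess (3 iterations), leaving out control 3 and 4 or taurine 1 and 2, a hepatocyte covariate, the methods' t-test, and identical probe sets counted once were added after seeing the data. No scan dates or array batches are given in the sources used here.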

Results

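Gene expression was measured in hind leg skeletal muscle of newborn male Wistar rats from 3 maternal diets that began on day 1 of gestation. Dams ate either control food or food low in protein, and a further low protein group drank water with 2% w/v taurine, a sulphur-containing amino acid derivative. Each of the 12 arrays held pooled RNA from 3 male newborns of 1 dam, and there were 4 arrays per group, so the dam was the replicate. The values covered 18957 detected probe sets on a log2 scale. The median of an array lay between 7.66 and 7.67 in the controls, between 7.73 and 7.75 with low protein and between 7.71 and 7.74 with added taurine. The number of arrays limits the precision.

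The composition of the control arrays differed. The mean of 23 hepatocyte markers, a list written after the values had been seen, was 6.69 in control 1 and 6.92 in control 2, and 10.76 in control 3 and 11.79 in control 4. In the 8 arrays of both low protein groups it lay between 6.74 and 8.05. Albumin (Alb) reached 13.37 in control 3 and 13.55 in control 4, against 7.25 in control 1 and 8.52 in control 2. It was at 11.43 in low protein 2 and 10.38 in low protein plus taurine 2, and between 8.02 and 9.31 in the other arrays of these groups. Without control 3 and control 4 the hepatocyte markers had a median of 0.309 in low protein against control. Leaving out these arrays thus did not make the groups equal in these markers. The marker median relative to control was -1.144 in low protein 2, against -2.046, -2.294 and -2.151 in low protein 1, 3 and 4. Control 1 and control 2 were at -2.213 and -2.107, so low protein 2 stood apart. Of the 23 markers 0 were in another list, and 1 lay above the array median in both control 1 and control 2. Control 3 and control 4 also stood apart on the first principal component, which held 43.1% of the variance.

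**Figure D1:**
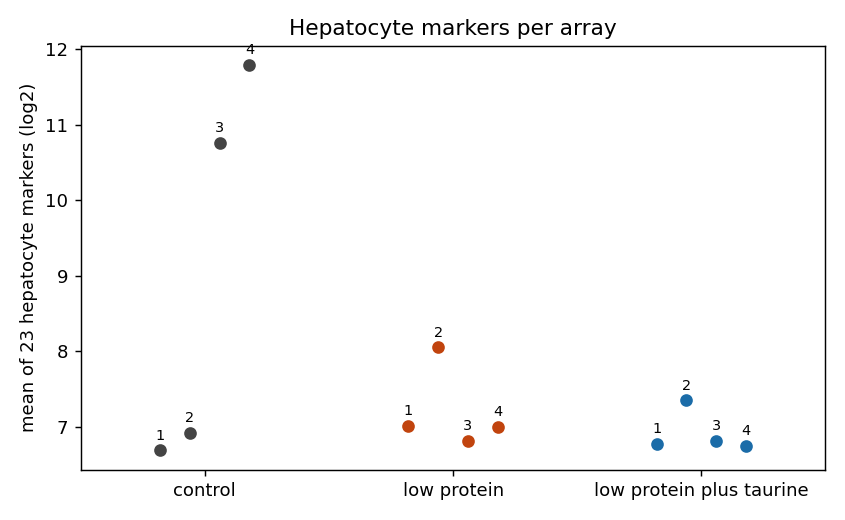
Mean log2 value of 23 hepatocyte markers on each array (vertical axis), by diet group (horizontal axis), with 1 point per array and the replicate number above it. Control 3 and control 4 lie at 10.76 and 11.79, and the other arrays lie between 6.69 and 8.05.

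The first comparison asked how a maternal low protein diet changed the newborn muscle. Lrrn1 (probe set 10857541), a leucine-rich repeat membrane protein, rose from 8.42 ± 0.08 to 9.19 ± 0.20 (SD, n = 4; limma adjusted p = 0.00417), a log2 fold change of 0.77 with a standard error of 0.10. Galnt5, an enzyme that starts O-glycosylation, rose by 0.65 (SE 0.10), and Pdlim2 and Mchr1 rose by 0.71 and 0.70. Slc6a6 (probe set 10857314), the membrane transporter that takes up taurine, rose from 8.22 ± 0.12 to 8.66 ± 0.10 (SD, n = 4; limma adjusted p = 0.00487). The list of fatty acid synthesis and lipid storage (camera adjusted p = 0.319, and 0.0493 without control 3 and control 4) and the adipocyte list (median 0.429, camera adjusted p = 0.968, with array medians relative to control of 1.15, -0.198, 0.069 and 0.41 in low protein 1 to 4) did not pass. Among single genes, the retinol-binding protein gene Rbp7 rose by 1.16 (SE 0.29), the glycerol channel gene Aqp7 by 1.12 (SE 0.39), Angptl4, an inhibitor of lipoprotein lipase, by 0.74 (SE 0.25) and the lipid droplet gene Cidea by 0.73 (SE 0.19). After cyclic loess normalization, chosen after seeing the data, Aqp7 was at 0.96 (limma adjusted p = 0.127), Angptl4 at 0.58 (0.139) and Cidea at 0.61 (0.0545). Without control 3 and control 4, Rbp7 was at 1.08 (limma adjusted p = 0.0622) and Angptl4 at 0.88 (0.0662). The clock gene Per1 rose by 0.89 (SE 0.32), and was at 0.75 after cyclic loess (limma adjusted p = 0.147) and at 1.02 without control 3 and control 4 (0.0902). The 12 largest falls were led by the metallothionein gene Mt2A at -1.51 (SE 0.49) and held genes that the liver expresses, such as Creb3l3 at -1.44, Apoc4 at -1.41, Proc at -1.35, Mbl2 at -1.27 and the transcription factor Hnf4a at -1.11. Without control 3 and control 4, the fold changes of these genes shrank to -0.62 for Mt2A, -0.26 for Creb3l3, -0.27 for Apoc4, -0.23 for Proc, -0.32 for Mbl2 and -0.36 for Hnf4a, and their adjusted limma p was 0.288, 0.0814, 0.0223, 0.0882, 0.0215 and 0.0224 in that order. After cyclic loess their fold changes were -1.57, -1.39, -1.45, -1.38, -1.21 and -1.07 in the same order, and the adjusted p lay between 0.0572 for Mt2A and 0.0862 for Creb3l3. In control 1 and control 2, Apoc4 (6.96 and 7.03), Mbl2 (6.49 and 6.6) and Hnf4a (6.71 and 6.83) were dim. Without control 3 and control 4, level bins 1 to 3 of 10 had medians from -0.13 to -0.058, and the 23 hepatocyte markers had a median of 0.309. The remaining falls are therefore not read as a fall of liver transcripts.

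Of the 39 fixed lists, 5 passed camera in this comparison. Of 30 proteasome genes, which encode the main protein-degrading complex, 13 rose and 0 fell, and 13 rose when adjusted over the list alone (median 0.176, camera adjusted p = 0.0301). Psmd3 rose by 0.29 (SE 0.06) and Psma4 by 0.25 (SE 0.05). After cyclic loess 0 proteasome genes rose, the median was 0.0365 and the adjusted p was 0.529. Of 18 endothelial markers 10 rose and 0 fell, and 11 rose when adjusted over the list alone, with Tie1 at 0.22, Esam at 0.26 and Sox18 at 0.43, against 1 that rose after cyclic loess (camera adjusted p = 0.0477, 0.331 after cyclic loess and 0.233 without control 3 and control 4). Of 15 erythroid markers 2 fell and 1 rose, and 2 fell when adjusted over the list alone (median -0.506, camera adjusted p = 0.000829). Klf1, an erythroid transcription factor, fell by 0.51 (SE 0.14) and Hbb-b1, a beta globin gene, fell by 0.34 (SE 0.10). Without control 3 and control 4 the erythroid list had a median of 0.0701 and an adjusted p of 0.447. Of 24 immediate early genes, 1 rose (Nr4a2, at 0.47 with SE 0.07) and 1 fell (Egr3, at -0.24), while the median was -0.103 and 1 rose and 0 fell when adjusted over the list alone (camera adjusted p = 0.0301, and 0.134 after cyclic loess). Its median was -0.262 and its adjusted p 5.21e-06 without control 3 and control 4, while its array medians in low protein, from -0.117 to 0.013, lay within those of the 4 controls, from -0.196 to 0.162. Of 12 neutrophil and mast cell markers, 1 fell, Camp at -0.89, and 0 did when adjusted over the list alone (median -0.196, camera adjusted p = 0.0301, 0.067 without control 3 and control 4 and 0.253 after cyclic loess). Camp was at -0.21 without control 3 and control 4 (limma adjusted p = 0.0607) and at -0.75 after cyclic loess (0.125). With an estimated correlation all 5 lists had an adjusted p = 0.987. The fry adjusted p was 0.02 for the proteasome, 0.00458 for endothelial, 0.278 for erythroid, 0.176 for neutrophil and mast cell and 0.814 for immediate early genes. Without control 3 and control 4 the lists of oxidative phosphorylation (median -0.0232, camera adjusted p = 0.0042), fatty acid uptake and oxidation (0.353, 0.0042), aminoacyl-tRNA synthetases (0.194, 0.0288) and cholesterol synthesis (0.336, 0.0288) passed as well, of which only oxidative phosphorylation did so after cyclic loess (0.0129). In the circadian clock list 10 of 16 genes rose and 0 fell, and 11 rose when adjusted over the list alone, although the list did not pass camera (adjusted p = 0.0783), and 3 rose after cyclic loess and 4 without control 3 and control 4. In the insulin and IGF signalling list 12 of 32 genes rose and 0 fell, and 12 rose when adjusted over the list alone (camera adjusted p = 0.229, fry adjusted p = 0.00102), against 3 after cyclic loess and 8 without control 3 and control 4. Over all probe sets 4127 of 18957 rose, and in the eighth of 10 equal bins by mean level 715 rose and 75 fell. The insulin and IGF count is therefore not read as particular to that list. Igf1, insulin-like growth factor 1, rose by 0.15 (SE 0.04), and was at 0.07 after cyclic loess (adjusted p = 0.239). Igf2 at -0.04, Igf1r at 0.04, Insr at 0.08, Irs1 at 0.15, the glucose transporter gene Slc2a4 at 0.35, Ppargc1a at 0.38, Mstn at 0.28, Fbxo32 at 0.04, Trim63 at 0.26, Asns at 0.18, Cdo1 at 0.29, Csad at 0.03, Myod1 at 0.12, Myh3 at -0.05 and Myh7 at 0.13 did not pass. Myog, a myogenic transcription factor, rose by 0.27 (SE 0.09), and was at 0.13 after cyclic loess (adjusted p = 0.302). The hepatocyte markers had a median of -1.94, with 0 of 23 past the threshold, and of 9 pancreas markers, a list also written after the values had been seen, 3 fell.

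In all, 6390 of 18957 probe sets passed a limma adjusted p of 0.05 in low protein against control, of which 4127 were higher and 2263 lower. For 32.8% of probe sets the arrays of both groups did not overlap, against 2.86% by chance. The split by direction depended on the scaling: 64.6% of the calls were higher in the deposited values, 51.1% after a further quantile normalization (2982 calls), 29.4% after centring each array on its median (5122 calls) and 36.9% after cyclic loess (2564 calls). It was 86.3% among probe sets above the median level (3863 calls) and 80.9% among those with 1 symbol (3838 calls). Without control 3 and control 4, 3705 probe sets passed, of which 55.1% were higher, and leaving out a single array gave 4211 without control 3, 4235 without low protein 2 and 3929 without low protein 3.

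**Figure D2:**
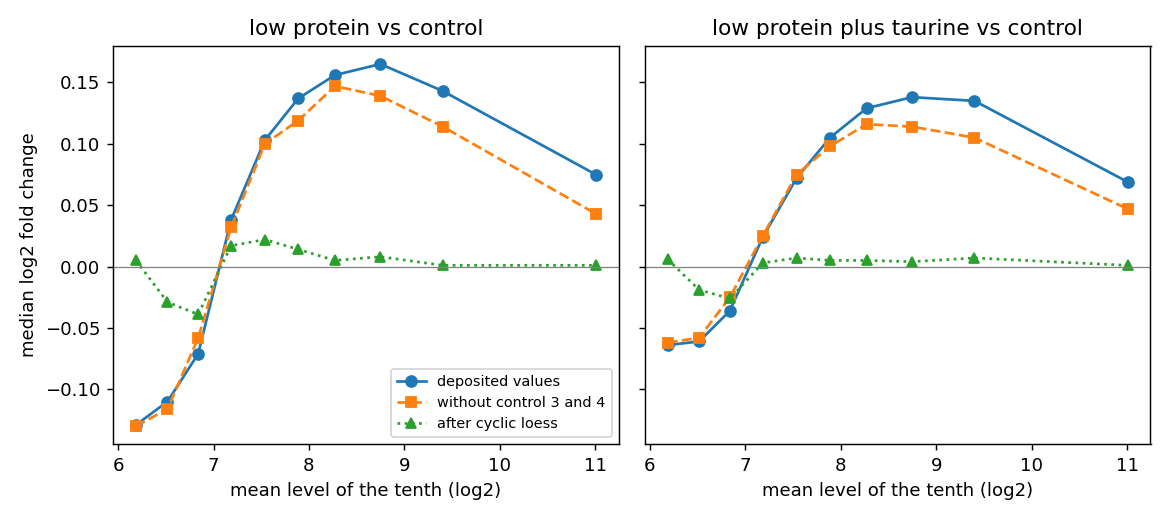
Median log2 fold change (vertical axis) in 10 bins of equal size of probe sets ordered by mean log2 level (horizontal axis), for low protein (left) and low protein plus taurine (right) against control. Lines show the deposited values, those without control 3 and 4, and those after cyclic loess. In the deposited values the low protein median goes from -0.129 in the dimmest bin to 0.165 in a bright bin, and after cyclic loess no bin lies further from 0 than -0.039.

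The second comparison asked how the muscle of newborns differed from control when the mothers received taurine with the low protein diet. Cilp, a cartilage and tendon matrix protein gene, rose from 7.62 ± 0.05 to 8.28 ± 0.20 (SD, n = 4; limma adjusted p = 0.00781). Klhl38 rose by 0.74 (SE 0.16), the small GTPase gene Rrad by 0.71 (SE 0.15), Lgi1 by 0.67, the connective tissue growth factor gene Ccn2 by 0.64 and the fast myosin gene Myh2 by 0.62. After cyclic loess Ccn2 was at 0.52 (limma adjusted p = 0.0805) and Myh2 at 0.54 (0.075). Without control 3 and control 4, Klhl38 was at 0.58 (limma adjusted p = 0.086), Rrad at 0.57 (0.0895), Ccn2 at 0.47 (0.146) and Myh2 at 0.63 (0.101). Mgst1, a microsomal glutathione transferase, fell by 2.09 (SE 0.54), and without control 3 and control 4 it was lower by a log2 fold change of -1.15 with an adjusted p of 0.149. The histone genes Hist1h2af and Hist3h2ba fell by 0.49 and 0.44. Slc6a6 was at 8.28 ± 0.11 against 8.22 ± 0.12 in control (SD, n = 4; limma adjusted p = 0.564). Slc2a4 rose by 0.56 (SE 0.16) and Mstn, which encodes the muscle growth inhibitor myostatin, by 0.58 (SE 0.14). They were at 0.43 and 0.45 after cyclic loess (adjusted p of 0.142 and 0.0784), and at 0.38 and 0.46 without control 3 and control 4 (0.23 and 0.118). For both genes the arrays of the groups overlapped. Slc2a4 was at 9.42 and 9.46 in taurine arrays 1 and 2 and at 8.82 and 8.72 in arrays 3 and 4. It was at 8.69 and 8.75 in control 1 and control 2.

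Of the 39 lists, 9 passed camera. Of 16 circadian clock genes 7 rose and 0 fell, and 10 rose when adjusted over the list alone (median 0.377, camera adjusted p = 0.00106, and 0.000157 after cyclic loess, where 4 rose). Nr1d2 rose by 0.44 (SE 0.06), Npas2 by 0.38, Nr1d1 by 0.44 and Per3 by 0.48. Of 25 sarcomere and excitation-contraction coupling genes 9 rose and 0 fell, and 14 rose when adjusted over the list alone, including Jph1 at 0.39 (SE 0.06), Clcn1 at 0.34 and Smyd1 at 0.33 (camera adjusted p = 0.00106, 0.194 without control 3 and control 4, and 1.12e-05 after cyclic loess, where 2 rose). In the list of myogenic regulators 6 of 23 rose, such as the acetylcholine receptor genes Chrnd at 0.32 and Chrna1 at 0.38 (camera adjusted p = 0.022, and 0.374 without these 2 arrays), and 8 rose when adjusted over the list alone. After cyclic loess 0 of them rose and 1 fell (camera adjusted p = 0.0313), and Chrnd was at 0.19 (limma adjusted p = 0.071) and Chrna1 at 0.27 (0.0806). In the extracellular matrix list 9 of 34 rose, such as Bgn at 0.25, Sparc at 0.22 and Timp3 at 0.41 (camera adjusted p = 0.0209, and 0.491 without these 2 arrays), and 13 rose when adjusted over the list alone and 2 after cyclic loess (camera adjusted p = 0.0274). Of 21 cartilage and bone markers 2 fell, Matn1 at -0.39 and Col9a2 at -0.35, and 2 fell when adjusted over the list alone, while the list's median of 0.0117 and mean of -0.0247 differed in sign (camera direction lower, camera adjusted p = 0.00741, and 0.118 after cyclic loess). In 4 further lists that passed, 0 members did so: 13 adipocyte markers had a median of -0.323 (camera adjusted p = 0.00106), 15 erythroid markers of -0.315 (0.00179, and 0.337 without control 3 and control 4), 35 cell cycle genes of -0.0199 (0.0101, and 0.142 without these 2 arrays) and 34 genes of fatty acid uptake and oxidation of -0.0201 (0.0467, and 0.361 without them). Without control 3 and control 4 these medians were -0.494, 0.267, 0.0211 and 0.183 in that order. When adjusted over the list alone 0 members of these 4 lists passed. With an estimated correlation all 9 had an adjusted p = 0.904. The fry adjusted p was 0.00534 for the clock, 0.0279 for the sarcomere and the matrix and 0.0119 for the myogenic list, and between 0.375 and 0.928 for the other 5. The cell cycle and fatty acid oxidation lists, with a fry adjusted p of 0.928 each, thus passed only relative to the other genes. After cyclic loess the immediate early (0.00068), fast fibre (0.00635), glycolysis (0.0114), slow fibre (0.0333) and oxidative stress (0.0154) lists passed as well, the last of them lower. Without the taurine arrays 1 and 2, in which the immediate early genes had medians of 0.53 and 0.72 relative to control, the adjusted p was 0.103 for the clock list, 0.145 for the sarcomere list, 0.0708 for the myogenic list, 0.416 for the matrix list, 0.217 for cartilage and bone, 0.516 for the cell cycle and 0.416 for fatty acid oxidation, and 0.00118 for both the adipocyte and the erythroid list. The hepatocyte median was -2.11, with 0 of 23 past the threshold, and the pancreas median was -0.129, with 1 of 9 higher.

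In total 2616 probe sets passed, of which 1934 were higher and 682 lower (73.9% higher). For 20.2% of probe sets the arrays of both groups did not overlap, against 2.86% by chance. The share of higher calls was 46.1% after a further quantile normalization (1201 calls), 32.9% after centring on the median (1822 calls) and 29.3% after cyclic loess (1137 calls), and 86.9% above the median level (2468 calls) and 92.0% with 1 symbol (1542 calls). Single arrays decided the number: 620 passed without low protein plus taurine 1, 1717 without 3 and 1098 without 4 of that group, 748 without control 3 and 1580 without control 1. Without both control 3 and control 4 it was 907, of which 43.3% were higher, and without taurine arrays 1 and 2 it was 1013.

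The third comparison asked whether taurine changed the muscle of newborns on the low protein diet. Slc6a6 had a log2 fold change of -0.38 (SE 0.08) with taurine, and all 4 taurine arrays lay below all 4 low protein arrays. It did not pass over all probe sets (limma adjusted p = 0.347), and had an adjusted p of 0.00492 over the 18 genes of the taurine and sulphur amino acid list alone, the 1 member that passed there. The list as a whole did not pass camera (adjusted p = 0.195). Other genes with separate groups and the smallest p were Rbp7 at -1.44 (SE 0.29), the pentose phosphate enzyme gene Tkt at -0.35, Lpcat2 at -0.41 and Rab34 at -0.28 among the lower, and Ccn2 at 0.73, Esm1 at 0.31, the water channel gene Aqp4 at 0.32 and Pde8b at 0.33 among the higher. None of these passed, with an adjusted p of 0.347 each. Of 18957 probe sets 0 passed in limma, 2047 had an unadjusted p under 0.05, and 0 passed with the methods' t-test after Benjamini-Hochberg adjustment. A limma fit of only both low protein groups gave 1, the unnamed probe set 10715250, and without control 3 and control 4 that one and probe set 10812361 passed, higher with taurine by 0.60 and 0.43. They were chosen after their values were seen.

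**Figure D3:**
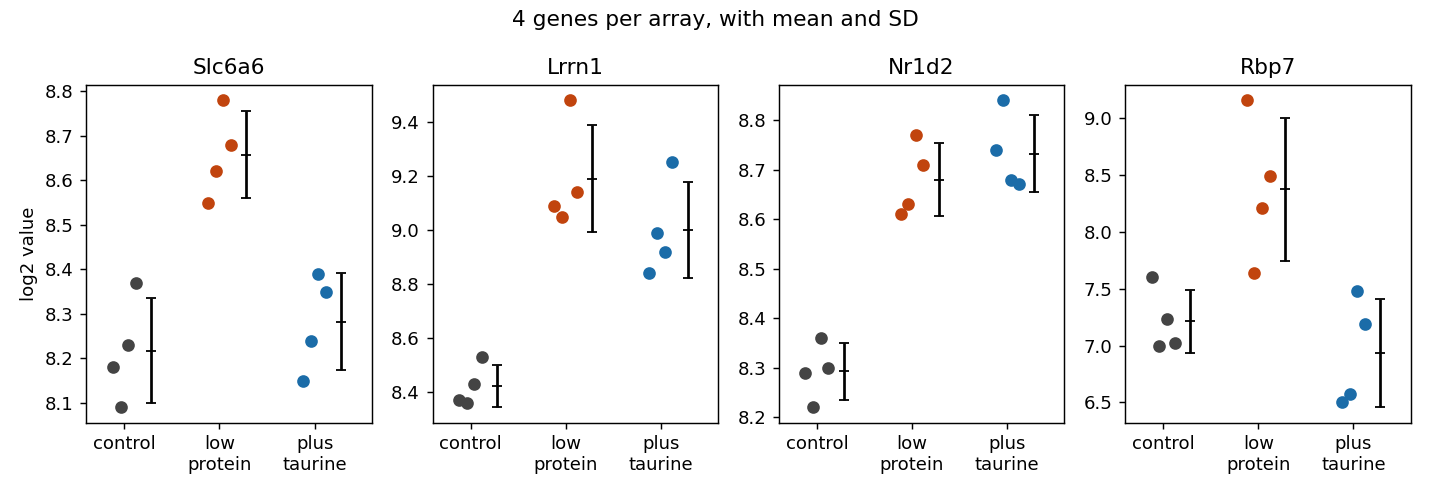
Log2 values of 4 genes on each array (vertical axis) by diet group (horizontal axis), with 1 point per array and the mean with SD beside it (4 arrays per group). Slc6a6 lies at 8.22 in control, 8.66 with low protein and 8.28 with low protein plus taurine.

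At the level of lists, 18 of 39 passed camera with its preset correlation, and 0 of their members passed over all probe sets. Lower with taurine as a list were the 13 adipocyte markers (0 with a positive fold change, median -0.645, camera adjusted p = 5.98e-06), of which 8 were lower when adjusted over the list alone, with Retn at -0.81, Plin1 at -1.04, Lipe at -0.50 and Aqp7 at -1.11. Also lower as lists were fatty acid synthesis and lipid storage (4 of 27 genes with a positive fold change, median -0.198, adjusted p = 5.65e-06), of which 2 were lower when adjusted over the list alone, with Fasn, the fatty acid synthase gene, at -0.33 and Dgat1 at -0.55, and fatty acid uptake and oxidation (9 of 34 positive, median -0.138, adjusted p = 0.00182), of which 2 were lower when adjusted over the list alone, Angptl4 at -1.06 and Cd36 at -0.28. The adipocyte and lipid storage lists share members such as Plin1 and Lipe, so their results are not separate support. Angptl4 is in both the fatty acid oxidation and the glucocorticoid list. The adipocyte median of single arrays relative to control was 1.15 in low protein 1, -0.198 in low protein 2, 0.069 in low protein 3 and 0.41 in low protein 4, and lay between -0.434 and -0.106 in the taurine arrays. Higher with taurine as a list were the immediate early genes (23 of 24 with a positive fold change, median 0.375, adjusted p = 5.36e-13), of which 15 were higher when adjusted over the list alone, with Fos at 1.22 (SE 0.29), Junb at 0.65 and Ccn1 at 1.14. Nuclear oxidative phosphorylation genes had a median of 0.0745 (adjusted p = 6.24e-05), fast fibre genes of 0.117 (0.00043), glycolysis genes of 0.0751 (0.00156), sarcomere genes of 0.0761 (0.00121) and glucocorticoid targets of 0.228 (0.00173). Within these, Gpd1 of the fast fibre list was at -1.35 and Angptl4 of the glucocorticoid list at -1.06, the 1 member of each list that passed when adjusted over the list alone. The lists of the tricarboxylic acid cycle (adjusted p = 0.0182), hypoxia (0.0163), slow fibre (0.0397) and interferon (0.0278, with 1 member higher when adjusted over the list alone) were also higher, and those of ribosome biogenesis (0.00604) and endothelial cells (0.0314) also lower. Proteasome genes had a median of -0.0785 (adjusted p = 0.000826), ribosomal protein genes of -0.0348 (0.00746) and cell cycle genes of -0.0915 (0.00194). With an estimated correlation these 18 lists had an adjusted p between 0.668 and 0.749, and none passed fry (adjusted p between 0.325 and 0.616). After cyclic loess the endothelial (0.104), interferon (0.116) and slow fibre (0.0609) lists no longer passed, and the other 15 did. Without the taurine arrays 1 and 2 the immediate early list (adjusted p = 2.74e-05), the adipocyte list (3.48e-07) and the lipid storage list (1.16e-06) still passed in the same direction, as did fatty acid oxidation (0.0375), ribosomal proteins (0.0375) and endothelial cells (0.0151). The oxidative phosphorylation (0.444), tricarboxylic acid cycle (0.351), glycolysis (0.507), fast fibre (0.962), glucocorticoid (0.155) and cell cycle (0.397) lists turned to the other direction without passing, and the hypoxia list turned and passed (0.0375). The sarcomere (0.414), proteasome (0.358), ribosome biogenesis (0.194), slow fibre (0.185) and interferon (0.358) lists no longer passed.

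An F test for any difference among the 3 diets passed in 4809 probe sets (25.4%). Fewer passed without control 1 (2687), control 3 (1919), low protein 2 (3127) or low protein 3 (2720). To compare both low protein groups, 200 probe sets were chosen on 2 control and 2 low protein arrays and measured on the others. The low protein shift was then 0.301 and the taurine shift 0.245, a ratio of 81.5% over 36 splits. Both shifts are measured against the same control arrays, whose deviations move both alike, and no value for a shift that is not kept was computed. Over splits, which share arrays, the SD was 53.6 percentage points and the range went from -155 to 222%, so the share was imprecise. Against control, 1521 probe sets were higher in both groups, 596 were lower in both, and 0 were higher with low protein and lower with taurine. Both comparisons share the 4 control arrays, which alone makes their calls overlap, and no value for unchanged groups was computed for these counts. Fold changes of both groups correlated across probe sets, which are not independent, with r = 0.849, against a mean of 0.583 for simulated unchanged groups that share the controls, whose range of -0.142 to 0.989 holds it. With the controls split the observed r averaged 0.567 over 6 splits (0.196 to 0.75), and the simulated mean was 0.114 (-0.927 to 0.96), so it too lay within the simulated range. The covariance was 0.0477, against a simulated mean of 0.0127 and a highest simulated value of 0.0851, so it lay within the simulated range.

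The authors' deposited table of low protein changes lists 895 probe sets, of which it marks 88 as fully and 195 as partly restored by taurine. The p-values in the authors' deposited table for low protein against control equal the normal tail of an equal-variance t statistic to within a relative difference of 7.07e-07 (for p above 1e-10), and 95 of them are printed as 0. They are thus without the Bonferroni adjustment that the deposited descriptions state for the selection, and over all 18957 probe sets a t reference with that adjustment passed 6. With a t reference of the matching degrees of freedom, the rule stated for the authors' deposited table gives 146 fully and 100 partly restored probe sets. In the limma fit 874 of the 895 passed, and all 895 had the direction of the authors' deposited table. The authors chose these probe sets on the same arrays, and both fold changes come from values of these arrays. The shared direction was thus largely fixed in advance, and neither count is independent support.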

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

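The tests in this part were chosen after the results were seen, on blood, diet, intensity, liver arrays, batch, fat, the early genes and other splits of the arrays, and only the test on the constancy of the liver excess was set before its result was seen. Of 510 groups of 4 arrays examined (41 lists and 129 of the genes that the naming rule takes), 22 held an array far from the other 3 by Dixon's ratio, or 4.31%, where chance gives about 5%.

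Liver transcripts in control 3 and control 4 were the first pattern. Blood alone does not account for them, since the hepatocyte excess over control 1 and 2 was larger than the erythroid excess by 3.25 log2 units. The control diet would raise all 4 arrays, yet only 2 control arrays lay above all 8 low protein arrays. Liver RNA in the pools would give 1 ratio of excess between both arrays for every marker; the SD over markers of its log2 was 0.523, above the limit of 0.5 set beforehand and below that of 1 that would exclude it. Liver RNA therefore stays open and cannot be told apart from other sources.

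The number of calls against control was the second pattern. No other split of the arrays gave as many calls for low protein against control (6390 calls, 1 of 35 splits as large, highest other 3). The same held for low protein plus taurine against control (2616 calls, 1 of 35, highest other 65) and for the F test (4809 calls, 1 of 100, highest other 22). A share of 1 of 35 is the smallest that 35 splits can give. The other splits also mix the diets, so a real difference widens their spread. These splits therefore do not exclude chance. For taurine against low protein the splits decide nothing, since with 0 calls each of the 35 is as large (highest other 2). After cyclic loess 2564 calls were left, 2086 of them also called in the same direction before it. Without the 2 liver arrays 3705 were left, 3072 of them also called in the same direction with all arrays. Neither step alone removed all calls. Both were not applied together, so whether a shift with intensity and the liver arrays account for the calls stays open. The 5th percentile of 4 control arrays lay above that of all 8 others, so a batch of arrays or dissections that follows the groups cannot be told apart from the diet.

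The third pattern was lower adipocyte markers and higher immediate early genes with taurine. Without low protein 1, the array medians of the adipocyte markers still differed by -0.381 (SE over arrays 0.159, 2.4 times its SE against a limit of 2.31). That narrow margin used a spread pooled with the controls, and the array was picked after its value was seen. Low protein 2 also lay within the range of the taurine arrays, so low protein 1 alone is not excluded. In 3 low protein arrays most markers lay above all taurine arrays. That count restates the pattern, so it cannot tell more fat in several low protein pools from less fat in the taurine pools. Against control the adipocyte list had a camera adjusted p of 0.968 with low protein and of 0.00106, lower, with taurine. Its fry adjusted p was 0.35 and 0.375, so neither stood apart from control there. Whether taurine arrays 1 and 2 alone account for the early genes stays open, since without them the array medians differed by 0.172 (SE over arrays 0.108) and the other taurine arrays, at 0.12 and 0.132, lay within the range of the controls. Whether the diet changed fat content or dissection did so was not tested.

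Among list medians relative to control, these arrays stood apart, with Dixon's ratio: slow fibre genes in control 4 (0.897), endoplasmic reticulum stress genes in low protein 3 (0.839), and, with low protein plus taurine, leukocytes in array 1 (0.861), skin keratinocytes in array 3 at 1.14 (0.87) and cartilage and bone in array 4 (0.834). Among genes in the controls they were Plcd4 (0.87), Gypc (0.9) and Kif2c (0.896) in control 1, Npas2 in control 3 (0.849), and Col9a2 (0.876) and Slc13a4 (0.892) in control 4. In low protein they were Esm1 (0.881) and Klf1 (0.887) in array 2, Nr1d1 (0.848) and Unc45b (0.846) in array 3, and Igf1 (0.83), Igf1r (0.88), Nipal1 (0.924) and Rrad (0.887) in array 4. In low protein plus taurine they were Plcd4 in array 1 (0.853), Igf1 in array 2 (0.848) and Zfp185 in array 3 (0.836).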

How the results depend on the processing

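Added after seeing the data were cyclic loess, the hepatocyte covariate, the methods' t-test, identical probe sets counted once, and leaving out control 3 and 4 or taurine 1 and 2; the cause of each change was not tested unless given. Low protein against control (6390 calls) went to 3863 above the median level and 3838 with 1 symbol (fewer probe sets tested), 2982 after quantile normalization, 3338 at a fold of at least 1.2, 3705 without control 3 and 4, 2564 after cyclic loess and 4079 with the methods' t-test; leaving out 1 array gave 3929 to 6621. Low protein plus taurine against control (2616) went to 1353 in a fit of only both groups (fewer arrays), 1542 with 1 symbol, 1201 after quantile normalization, 4276 with array weights, 5183 at an adjusted p under 0.1, 1514 at a fold of at least 1.2, 907 without control 3 and 4, 1137 after cyclic loess, 1180 with the hepatocyte covariate, 1013 without taurine 1 and 2 and 491 with the methods' t-test; leaving out 1 array gave 620 to 2742. Taurine against low protein (0) gave 1 in a fit of only both groups and 2 without control 3 and 4, all unnamed probe sets, and 0 when leaving out any 1 array. The F test for any difference among the 3 diets (4809) went to 2832 with 1 symbol, 1996 after quantile normalization, 7687 at 0.1, 1722 without control 3 and 4, 1874 after cyclic loess and 2675 with the hepatocyte covariate; leaving out 1 array gave 1919 to 4829. The share kept ranged from 73.7 to 93.4 percent on leaving out 1 taurine array (other arrays were not left out there), and r from 0.796 to 0.882 on leaving out any 1 array. With the replicate block the calls were 5456, 1974, 0 and 3622; pairs of the same number did not deviate together (3 of 12 over 0.1), so the numbers only name the arrays.

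Camera's direction is relative to the other genes, so it can turn while a list's median keeps its sign. Fry's direction is against no change. For lists that passed in the main fit or in the setting named, the direction turned as follows, with adjusted p. In low protein against control it turned for fatty acid uptake above the median level (0.047). In low protein plus taurine against control it turned for fatty acid uptake with fry (0.928), without control 3 and 4 (0.361) and with the hepatocyte covariate (0.819), for erythroid markers in the last 2 settings (0.337 and 0.478), and without taurine 1 and 2 for the cell cycle (0.516) and hypoxia (0.00118). In taurine against low protein it turned without taurine 1 and 2 for oxidative phosphorylation (0.444), the tricarboxylic acid cycle (0.351), glycolysis (0.507), atrophy and autophagy (0.0375), fast fibre (0.962), cell cycle (0.397), glucocorticoid (0.155) and hypoxia (0.0375) genes. Some lists that passed in neither turned as well and are not all given. Examples in low protein against control after cyclic loess are fatty acid uptake (0.818) and aminoacyl-tRNA synthetases (0.732), whose medians stayed positive (0.0654 and 0.0132). Another is the immediate early list (0.649) in low protein plus taurine against control without taurine 1 and 2. Of the named genes called against control, cyclic loess ended the call of 25 of 40 in low protein and 16 of 42 in low protein plus taurine, leaving out control 3 and 4 that of 19 and 25, and quantile normalization that of 23 and 14, and no named gene that passed changed direction. In low protein against control the dimmest of 10 level bins held 49 higher and 465 lower calls, the eighth 715 and 75, and the brightest 354 and 106; a limit by signal over background was not tested otherwise.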

Other observations

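In some further lists that did not pass camera in low protein against control, picked out after their counts were seen, single members rose, as 4127 of all 18957 probe sets did. Of 33 ribosome biogenesis genes 15 rose and 1 fell (camera adjusted p = 0.111), and 4 rose and 4 fell after cyclic loess. Of 20 aminoacyl-tRNA synthetases 6 rose (adjusted p = 0.191), against 0 after cyclic loess and 8 without control 3 and control 4, where the list passed (adjusted p = 0.0288). Of 20 markers of fibroblasts and tendon 9 rose and 2 fell (adjusted p = 0.469), and of 15 markers of pericytes and smooth muscle 6 rose (adjusted p = 0.215), against 0 and 1 that rose after cyclic loess. Skin keratinocyte markers were high on single arrays, with a median of 1.29 in low protein 4 and 1.14 in low protein plus taurine 3 relative to control.

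A hypothesis, whose test was chosen after its values were seen, is that taurine in the drinking water may lower Slc6a6, the taurine transporter, in newborn muscle. All 4 taurine arrays lay below all 4 low protein arrays, and the limma p adjusted over the taurine and sulphur list alone was 0.00492, while over all probe sets it was 0.347. The gene belonged to the fixed set, but it was singled out from that set, and its test chosen, on the same data. No group received taurine on the control diet, so an effect of taurine apart from the low protein diet was not tested. A difference between the arrays or dissections of both groups stays open.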
